A study of Mus musculus with 12 samples.

How the data were processed

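RNA was measured in hematopoietic stem cells (HSCs) of female C57BL/6 mice, the bone marrow cells that renew themselves and give rise to every blood lineage. Per the labels' protocols, cells without markers of mature lineages were sorted for Sca-1 and c-kit and against CD48 and CD135. The lineage cocktail held antibodies against Gr-1 (granulocytes), TER-119 (erythroid cells), B220 and IgM (B cells), NK1.1 and T cell receptors. The sorted cells were divided by CD150 into a low fraction, the lymphoid-biased Ly-HSCs, and a high fraction, the myeloid-biased My-HSCs. The labels give 18 months as the age of old mice and 8 to 10 weeks as that of young mice, while the protocol gives 8 to 12 weeks for the young. Each of the 4 groups held 3 libraries, from 3 independent groups of mice per the labels, so p-values measure the spread between pools of mice. Per the labels' protocols, RNA was extracted with Direct-Zol, libraries were made with the KAPA stranded mRNA-seq kit, and they were read as paired ends on a HiSeq3000.

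The deposited table holds FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, for each gene and library, as normalized by the authors, per the labels. The submitters' processing notes name bcl2fastq 2.17, STAR, DESeq2 and the GRCm38 (mm10) build, without saying which step each served. The gene annotation, the filter on genes and the rule for multi-mapped reads are not given in the sources used here. Of 14143 genes in the table, 14139 matched a GENCODE M21 gene identifier, 14125 of them protein coding among 22028 protein-coding genes of that annotation, and 314 were at 0 in all 12 libraries. Gene coordinates come from that annotation on GRCm38. How reads were split among near-identical genes is not given in the sources used here, so values of multigene families such as the class I and class II histocompatibility genes and the guanylate-binding proteins are uncertain. Genes of the fixed lists below that have no value here, among them the sort antigen Kit and the sex control Xist, were not analysed here. The Y-linked sex controls Kdm5d and Uty reached at most 0 and 0.005 FPKM in any library and fell under the filter given below.

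Read totals are unknown, since the unit removes them. FPKM summed to 211455 to 228391 per library, and the 10 most abundant genes held 1.68% to 2.09% of that sum. Relative depth was estimated from low values, on the assumption that they are whole multiples of what 1 fragment is worth. Of 262 checked ratios 59.9% lay within 0.05 of a whole number, against at most 16.8% with the units exchanged between libraries. The units were chosen to give such ratios at low values of the same libraries, so this comparison is not an independent check. The estimates are thus approximate, and rest on few ratios in the young libraries, such as 11 of 17 in young Ly-HSC library 1, 12 of 25 in young Ly-HSC library 3 and 8 of 21 in young My-HSC library 1. With old My-HSC library 2 set to 1.0, depth was 0.353, 0.699 and 0.565 in young Ly-HSC libraries 1, 2 and 3, and 0.613, 1.05 and 1.07 in the old Ly-HSC libraries. It was 0.729, 0.759 and 0.790 in the young My-HSC libraries, and 0.881, 1.0 and 0.773 in the old My-HSC libraries. The share of genes at exactly 0 was 34.1%, 25.0% and 28.4% in young Ly-HSCs, 22.3%, 13.3% and 14.1% in old Ly-HSCs, 26.1%, 20.3% and 19.3% in young My-HSCs, and 18.2%, 12.1% and 12.2% in old My-HSCs. Genes used by every cell are among those listed at 0, such as Atp5g2, an ATP synthase subunit, in young Ly-HSC library 1, so a value of 0 is reported as listed, with each library's value in place of a mean. By these estimates, depth alone does not account for the zeros, which were 12.2% in old My-HSC library 3 and 20.3% in young My-HSC library 2 at depths of 0.773 and 0.759, and their cause was not settled. The median SD of a gene on the log2 scale was 0.68 in young Ly-HSCs, 0.35 in old Ly-HSCs, 0.43 in young My-HSCs and 0.28 in old My-HSCs.

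Values were analysed as log2(FPKM + 1), with the 10900 genes that reached an FPKM of 1 in at least 3 libraries. A fold change is therefore on the log2(FPKM + 1) scale and understates the change of low genes. One group-means model over all 12 libraries was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, 8 residual degrees of freedom and 5.11 prior degrees of freedom. Contrasts were old minus young within each subset, My-HSCs minus Ly-HSCs within each age, the mean of each pair, and the interaction, which is the age effect in My-HSCs minus that in Ly-HSCs. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of each contrast, and genes with an adjusted p under 0.05 were called. Of 31 gene lists fixed before the data were examined, 29 had enough genes and were tested with limma's camera, which compares a list with all other genes at a preset inter-gene correlation of 0.01, with adjustment over the lists of a contrast. Camera was repeated with a correlation estimated per list. Direction in a list test is relative to the other genes. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 served for depth estimates, summaries and figures.

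The groups, the contrasts, the model, the lists, most alternatives and the rule for named genes were set before the data were examined. The rule names, in each simple contrast, the 10 largest increases and decreases among called genes whose libraries do not overlap between the groups, leaving out predicted gene models. Where fewer than 5 genes pass in a contrast or the interaction, it names the 10 genes with the smallest p as not passing. It adds the sort antigens and, per list, up to 4 called members with the smallest p, or up to 2 uncalled ones as values.

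The model was tested on simulated data with 200 of 10900 genes changed, 50 per size, in 5 simulations. For age in Ly-HSCs it recovered 20.4%, 60.4%, 87.2% and 94.0% of changes of 1, 2, 3 and 4 on the log2 scale, with 18.0% false among the called genes. For age in My-HSCs the shares were 17.6%, 57.6%, 85.2% and 92.8%, with 1.2% false. For subset in young mice they were 20.8%, 59.2%, 88.0% and 93.6%, with 24.3% false, and for subset in old mice 16.0%, 57.2%, 85.6% and 93.6%, with 0.6% false. With 1 weight per group, the false shares were 5.7%, 3.6%, 4.3% and 3.0% in the same order. In these simulations the equal-weight model was thus too permissive where young Ly-HSCs, the most variable group, enter a simple contrast. It was strict there for age in My-HSCs and subset in old mice. The simulated genes and libraries were drawn independently, without the pairing of old libraries described below, so false shares among the real calls may differ. The equal-weight model was kept because it was set before the data were examined, and the counts with group weights stand beside it.

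Replicate numbers were checked for pairing by correlating each library's deviations from its group mean between subsets. In old mice, same-numbered libraries correlated at 0.256, 0.233 and 0.21, so the numbers pair old libraries, by the data and not by a label. In young mice the values were 0.048, 0.003 and 0.002. Blocked fits are therefore given beside subset contrasts where they change a count or a call. Other alternatives were other pseudocounts, filters, scalings, variance models and weights, only the groups compared, the depth as a covariate, and leaving out each library in turn. Of the scalings, TPM multiplied all libraries by a similar factor, since FPKM summed to 211455 to 228391, and kept the pseudocount of 1. It therefore acted much as a smaller pseudocount. Chosen after seeing the data were the fits without the 4 libraries numbered 1, without the 4 lowest-weight libraries, with genes above 0 in all 12 libraries, with depth as a covariate, with a pseudocount of 5 and with 1 weight per group, and the list tests without the libraries numbered 1, with genes above 0 in all 12 libraries and with the block within age.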

Results

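Gene expression was measured by RNA-seq in Ly-HSCs (CD150-low, lymphoid-biased) and My-HSCs (CD150-high, myeloid-biased) from young and old female mice, with 3 libraries in each of the 4 groups. The values are FPKM as deposited. Unless stated otherwise, an error after ± is the SD over the 3 libraries of a group for an FPKM (n = 3) and the standard error from limma for a log2 fold change. Read totals are unknown, and the depth estimated from low values ran from 0.353 in young Ly-HSC library 1 to 1.07 in old Ly-HSC library 3, relative to old My-HSC library 2. Libraries of the young Ly-HSCs correlated least with each other, at 0.706 to 0.789 across genes, and those of the old My-HSCs at 0.875 to 0.965.

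The comparison of old with young Ly-HSCs addresses how the lymphoid-biased fraction changes with age, the subject of the series. Eya4, a transcriptional coactivator and phosphatase of the eyes-absent family, rose 22.9-fold, from 0.209 ± 0.325 FPKM in young to 26.2 ± 4.18 FPKM in old Ly-HSCs (log2 fold change 4.52 ± 0.47, adjusted p = 0.0014). Aldh1a1, a retinaldehyde dehydrogenase, rose 10.2-fold from 16.5 ± 12.2 to 150.0 ± 20.4 FPKM (adjusted p = 0.00424). Cd74, the invariant chain of class II histocompatibility molecules, rose 5.02-fold from 40.8 ± 5.77 to 211.6 ± 54.1 FPKM (adjusted p = 0.0014). Dtnbp1, which encodes dysbindin, was the 1 called gene that fell, by 0.89 ± 0.17 on the log2 scale, from 154.6 ± 8.36 to 84.1 ± 16.7 FPKM (adjusted p = 0.0459). On GRCm38, Eya4 (ENSMUSG00000010461.14) lies on chromosome 10 from 23102963 to 23350786, Aldh1a1 on chromosome 19 from 20492715 to 20643465, Cd74 on chromosome 18 from 60803848 to 60812652 and Dtnbp1 on chromosome 13 from 44922075 to 45002147.

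Other called genes that rose, among them some with larger fold changes than Aldh1a1 and Cd74, were listed at 0 in at least 1 young Ly-HSC library. Mab21l2 was listed at 0, 0 and 0.057 FPKM in the young and at 15.7, 9.43 and 18.2 FPKM in the old libraries (adjusted p = 0.00424). Cept1, a choline and ethanolamine phosphotransferase, went from 0, 1.65 and 0.107 to 28.95, 15.5 and 13.02 FPKM (adjusted p = 0.00453). Plscr2, a phospholipid scramblase, went from 0.094, 0 and 0 to 5.89, 14.2 and 14.9 FPKM (adjusted p = 0.0161). The interferon-induced Gbp6 stood at 0, 0.060 and 6.36 against 29.9, 19.97 and 31.6 FPKM (adjusted p = 0.0347). The stress-inducible Gadd45b stood at 0, 1.84 and 0 against 14.95, 7.17 and 18.1 FPKM (adjusted p = 0.0161). Cryl1, listed at 0 in all 3 young libraries, stood at 19.5, 7.55 and 8.31 FPKM in the old (adjusted p = 0.0421). Hmmr, a hyaluronan receptor of the mitotic spindle, went from 0, 1.02 and 1.51 to 41.7, 16.5 and 6.45 FPKM (adjusted p = 0.0438). Lyrm2 went from 0, 3.64 and 0.087 to 17.9, 14.3 and 12.6 FPKM (adjusted p = 0.0462). Bmpr1a, a type I receptor for bone morphogenetic proteins, rose from 0.025, 0.367 and 0 to 11.1, 6.44 and 6.52 FPKM (adjusted p = 0.0154).

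Genes that general literature reports as higher in aged HSCs rose as a list in Ly-HSCs. Of 41 tested, 39 were higher in old cells, with a median log2 fold change of 1.11 (camera adjusted p = 1.35e-11, and adjusted p = 0.0190 with an estimated correlation). All 6 called members rose, and 15 rose with p adjusted over the list alone. They include Aldh1a1, Plscr2, Sdpr, the caveolar protein cavin-2, from 4.64 ± 3.597 to 39.7 ± 3.14 FPKM (9.02-fold, adjusted p = 0.0161), and Gda, guanine deaminase, from 9.75 ± 4.54 to 37.1 ± 4.48 FPKM (3.81-fold, adjusted p = 0.0161). Antigen presentation genes also rose, with 15 of 18 higher and a median of 0.51 (camera adjusted p = 5.00e-04). The call was lost with an estimated correlation (adjusted p = 0.107 with an estimated correlation). Its called members were Cd74 and the nonclassical class I gene H2-Q7, from 134.7 ± 6.64 to 235.8 ± 34.3 FPKM (adjusted p = 0.0462), and 7 rose with p adjusted over the list alone. Cell cycle genes rose relative to other genes, with 46 of 47 higher and a median of 1.145 (camera adjusted p = 2.43e-06, and adjusted p = 0.404 with an estimated correlation). None of them was called, over all genes or adjusted over the list alone. The mitotic kinesin Kif20a stood at a log2 fold change of 3.53 ± 0.96 (adjusted p = 0.154) and Ube2c, of the anaphase-promoting machinery, at 3.35 ± 0.93 (adjusted p = 0.162). Markers of mature cells lay higher in the same comparison without passing, erythroid genes at 12 of 12 with a median of 0.92 (camera adjusted p = 0.0780), granulocyte markers at 3 of 3 with a median of 2.03 (camera adjusted p = 0.273), B lineage markers at 4 of 5 with a median of 1.43 (camera adjusted p = 0.232) and monocyte and macrophage markers at 6 of 8 with a median of 0.84 (camera adjusted p = 0.660). Old Ly-HSC library 1 stood highest among the old Ly-HSC libraries both in Itgam, at 159.98 against 19.4 and 28.3 FPKM, and in the cell cycle mean, at 4.155 against 3.98 and 3.34 on the log2 scale.

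HSC identity genes fell relative to the other genes in Ly-HSCs, with 9 of 24 higher and a median log2 fold change of -0.14 (camera adjusted p = 0.00796, and adjusted p = 0.404 with an estimated correlation). Their mean was slightly positive at 0.018. The call ended with quantile normalization (adjusted p = 0.224), without young Ly-HSC library 1 (adjusted p = 0.0605) or 2 (adjusted p = 0.172), and without the 4 libraries numbered 1 (adjusted p = 0.111). Its 1 called member was Ly6a, which encodes Sca-1, a marker of the sort itself. Ly6a rose 7.79-fold from 2.74 ± 1.34 to 31.4 ± 20.3 FPKM (adjusted p = 0.0440), and with p adjusted over the list alone 1 gene rose and 6 fell. The other sort antigens did not pass. Slamf1, which encodes CD150, stood at a log2 fold change of 0.78 ± 0.52 (adjusted p = 0.524). Flt3, which encodes CD135, stood at -0.057 ± 0.72 (adjusted p = 0.982) and Cd48 at 0.97 ± 0.82 (adjusted p = 0.633). The other 25 tested lists were not called, from an adjusted p of 0.0580 for nuclear oxidative phosphorylation genes, 44 of 54 of them higher, to 0.964. Among them, lymphoid priming genes had 7 of 15 higher (adjusted p = 0.778), with Il12a at 0.97 ± 0.33 (adjusted p = 0.231) and Gpr171 at 0.75 ± 0.26 (adjusted p = 0.249). Interferon response genes had 29 of 42 higher (adjusted p = 0.322) and p53 and senescence genes an adjusted p of 0.927. The called megakaryocyte list member Plek, or pleckstrin, rose from 29.7 ± 6.18 to 83.4 ± 26.0 FPKM (adjusted p = 0.0496).

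In all, 38 genes were called in Ly-HSCs, 37 higher and 1 lower in old cells, and 1450 genes had an unadjusted p under 0.05. Of the tested genes, 62.4% were higher in old cells, with a median log2 fold change of 0.18. That median was -0.009 with quantile normalization, 0.12 with median-of-ratios scaling and 0.22 as TPM, and 14, 24 and 33 genes were then called. With relative depth as a covariate 3 genes were called, 2 of them among the 38, and 2 of the 18 named called genes passed. Libraries did not overlap between the ages at 15.98% of genes, against 10% by chance, with 1251 higher and 491 lower. On simulated data 18.0% of the genes called in this contrast were false. With 1 weight per group, 9 genes were called, all 9 among the 38 and all higher, and 6 of the 18 named called genes passed. Leaving out young Ly-HSC library 1, 2 or 3 gave 59, 223 and 110 called genes, and 14, 17 and 15 of the 18 named genes passed. Leaving out old Ly-HSC library 1, 2 or 3 gave 8, 7 and 11 genes, with 6, 6 and 8 named genes passing. Without young My-HSC library 2 or 3, 14 and 19 were called, and without old My-HSC library 1, 2 or 3, 18, 14 and 14. The fit of the 6 Ly-HSC libraries alone called 0 genes by limma (950 at p under 0.05).

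**Figure D1:**
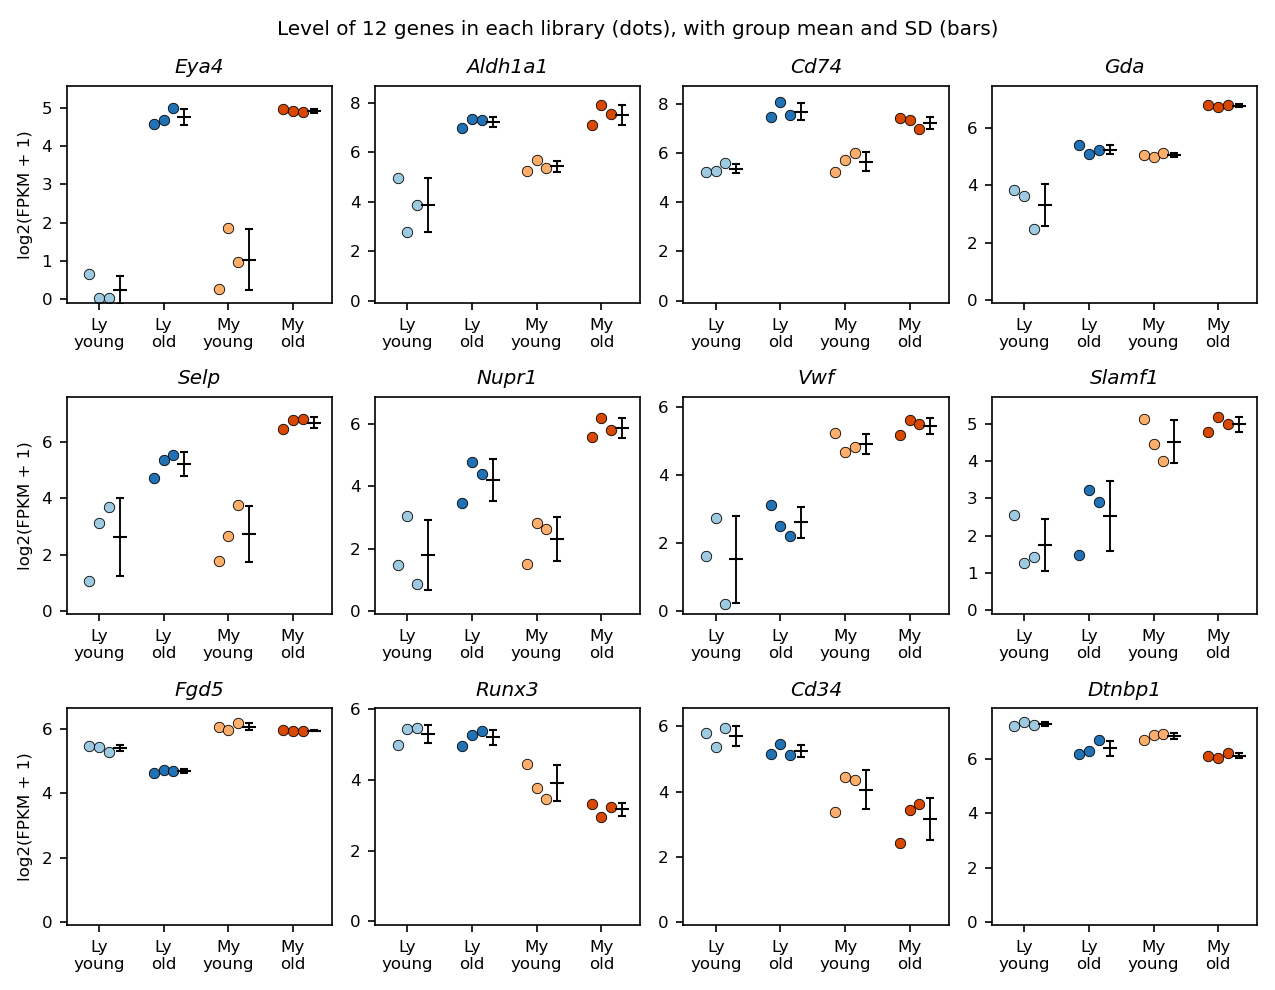
Expression of 12 named genes in young and old Ly-HSCs and My-HSCs on a log2(FPKM + 1) axis, with 1 dot per library and a bar for the group mean ± SD (n = 3). Eya4 and Cd74 lie higher in every old library of both subsets, and Cd34 and Runx3 lower in My-HSCs at both ages.

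The comparison of old with young My-HSCs gives the age effect in the myeloid-biased fraction. Selp, which encodes the adhesion molecule P-selectin, rose 15.2-fold from 6.79 ± 5.17 to 101.5 ± 12.9 FPKM (adjusted p = 0.0196). Eya4 rose 14.8-fold from 1.26 ± 1.24 to 29.2 ± 0.839 FPKM (adjusted p = 0.00767) and the stress-inducible regulator Nupr1 rose 11.7-fold from 4.34 ± 2.24 to 57.8 ± 13.2 FPKM (adjusted p = 0.0238). Cd74 rose 2.99-fold to 152.0 ± 23.8 FPKM from 51.0 ± 13.8 (adjusted p = 0.0196). Nes, the intermediate filament nestin, fell by 2.66 ± 0.41 on the log2 scale, from 6.83 ± 1.05 to 0.241 ± 0.207 FPKM (adjusted p = 0.0196). Ptpn7, a haematopoietic tyrosine phosphatase, fell by 1.29 ± 0.21 on that scale, from 44.9 ± 7.19 to 17.7 ± 1.52 FPKM (adjusted p = 0.0238). On GRCm38, Selp lies on chromosome 1 from 164115264 to 164150026 and Nes on chromosome 3 from 87971078 to 87980451.

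Among other called genes that rose, Mab21l2 was listed at 0 in all 3 young My-HSC libraries and at 11.3, 29.3 and 21.9 FPKM in the old (adjusted p = 0.00455). Plscr2 stood at 0, 2.28 and 1.18 against 25.0, 36.8 and 23.3 FPKM (adjusted p = 0.0159). The oxysterol receptor Gpr183 stood at 0.490, 0 and 0.095 against 5.36, 18.4 and 18.9 FPKM (adjusted p = 0.0196). The matrilin Matn4 stood at 0, 0.758 and 0.053 against 7.44, 10.4 and 12.9 FPKM (adjusted p = 0.0196). The nuclear receptor Rorb rose 8.60-fold from 0.160 ± 0.148 to 8.96 ± 1.03 FPKM (adjusted p = 0.0133). Tdrd9, of the piRNA pathway, stood at 0, 0.167 and 0.333 against 6.73, 11.8 and 7.90 FPKM (adjusted p = 0.0263), and Bmpr1a at 0, 0.513 and 0.571 against 7.71, 9.17 and 9.53 FPKM (adjusted p = 0.0196). Osmr, the oncostatin M receptor, stood at 0, 0.006 and 0.017 against 3.69, 3.61 and 2.83 FPKM (adjusted p = 0.0263). The chaperone clusterin, Clu, rose 7.04-fold to 30.4 ± 9.98 FPKM (adjusted p = 0.0238) and the growth factor Tgfb3 6.39-fold to 6.69 ± 2.70 FPKM (adjusted p = 0.0359).

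In My-HSCs the HSC ageing list rose with 38 of 41 genes higher and a median log2 fold change of 1.82 (camera adjusted p = 1.33e-31, and adjusted p = 5.65e-04 with an estimated correlation). All 9 called members rose, Rorb, Plscr2, Gpr183 and Selp with the smallest p, and 28 rose with p adjusted over the list alone. Antigen presentation genes rose with 14 of 18 higher and a median of 0.68 (camera adjusted p = 7.11e-06, and adjusted p = 0.0318 with an estimated correlation). Cd74 was the 1 called member, and 7 rose with p adjusted over the list alone. Chromatin regulators fell relative to the other genes, with 14 of 40 higher and a median of -0.23 (camera adjusted p = 0.00952, and adjusted p = 0.253 with an estimated correlation). So did DNA repair genes, with 15 of 39 higher and a median of -0.18 (camera adjusted p = 0.0309, and adjusted p = 0.415 with an estimated correlation). Neither list had a called member. The DNA demethylase Tet1 stood at -0.86 ± 0.29 (adjusted p = 0.481), the maintenance methyltransferase Dnmt1 at -0.38 ± 0.19 (adjusted p = 0.725). The repair helicase Ercc2 stood at -0.73 ± 0.21 (adjusted p = 0.350) and the ligase Lig1 at -0.66 ± 0.27 (adjusted p = 0.574). The chromatin call ended without young My-HSC library 3 (adjusted p = 0.0665). The DNA repair call ended without young My-HSC library 2 (adjusted p = 0.246) or 3 (adjusted p = 0.0992) or old My-HSC library 3 (adjusted p = 0.0854).

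Myeloid priming genes rose as a list in My-HSCs with 15 of 18 higher and a median of 1.24 (camera adjusted p = 0.00114, and adjusted p = 0.415 with an estimated correlation). Immediate early genes rose with 13 of 15 higher and a median of 1.28 (camera adjusted p = 0.00308, and adjusted p = 0.380 with an estimated correlation), and the 3 tested granulocyte markers rose with a median of 2.84 (camera adjusted p = 0.0226, and adjusted p = 0.380 with an estimated correlation). None of their members was called over all genes, and 3 immediate early genes rose with p adjusted over the list alone. Markers of mature myeloid cells stood highest in old My-HSC library 1. The integrin Itgam stood at 124.5, 23.5 and 18.0 FPKM in old My-HSC libraries 1, 2 and 3 against 0, 6.69 and 3.29 FPKM in the young (adjusted p = 0.450), and the neutrophil protease Mmp9 stood at 69.3, 4.32 and 3.53 against 0, 0.041 and 1.38 FPKM (adjusted p = 0.619). Junb, an immediate early factor, stood at 135.9 ± 54.7 in young and 329.9 ± 12.9 FPKM in old My-HSCs (adjusted p = 0.0757). The myeloid call ended without old My-HSC library 1 (adjusted p = 0.323) or all 4 libraries numbered 1 (adjusted p = 0.1004), and with only the genes above 0 in all 12 libraries (adjusted p = 0.389). The immediate early call ended without young My-HSC library 1 (adjusted p = 0.0732) or the 4 libraries numbered 1 (adjusted p = 0.1004). The granulocyte call ended without old My-HSC library 1 (adjusted p = 0.166) or young My-HSC library 2 (adjusted p = 0.0884) or 3 (adjusted p = 0.0566). Of the 22 lists not called, from adjusted p = 0.0512 for NF-kB and inflammatory genes to 0.937, cell cycle genes had 27 of 47 higher, with a median of 0.16. Camera still placed the list below the other genes (adjusted p = 0.441). Their Mcm7 stood at -0.78 ± 0.25 (adjusted p = 0.414). Lymphoid priming genes had 11 of 15 higher (adjusted p = 0.441), with the adaptor Lax1 at -1.02 ± 0.26 (adjusted p = 0.204). The sort antigens Slamf1 at 0.46 ± 0.52 (adjusted p = 0.950), Flt3 at 0.14 ± 0.72 (adjusted p = 0.995), Cd48 at 0.72 ± 0.82 (adjusted p = 0.951) and Ly6a at 1.45 ± 0.55 (adjusted p = 0.537) did not pass.

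In all, 23 genes were called in My-HSCs, 21 higher and 2 lower in old cells, with 786 at an unadjusted p under 0.05. As TPM, which acted much as a smaller pseudocount, or with a pseudocount of 0.1, 1 gene was called, and 1 of the 16 named called genes passed in each. Median-of-ratios scaling called 24 and quantile normalization 25. Libraries did not overlap at 19.1% of genes, against 10% by chance, with 1228 higher and 850 lower. With 1 weight per group, which suited the small spread of old My-HSCs, 71 genes were called, 67 higher and 4 lower, and all 23 were among them. On simulated data 1.2% of the genes called with equal weights were false. The count was 36 without young Ly-HSC library 1, 12 and 10 without old Ly-HSC library 2 or 3. It was 2, 4 and 10 without young My-HSC library 1, 2 or 3, and 2, 0 and 0 without old My-HSC library 1, 2 or 3 (limma, 576 and 578 genes at p under 0.05 for the counts of 0). Of the 16 named called genes, 2, 3 and 7 passed without young My-HSC library 1, 2 or 3, and 2, 0 and 0 without old My-HSC library 1, 2 or 3.

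**Figure D2:**
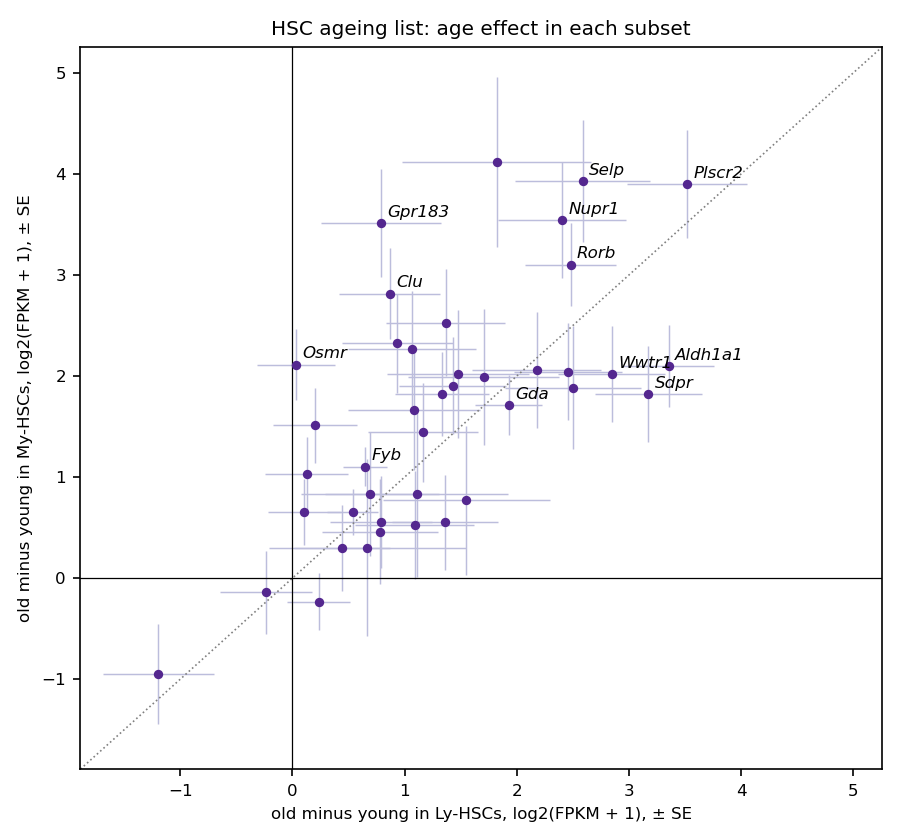
Age effect (log2 fold change, old minus young, ± standard error) of the 41 genes of the HSC ageing list in Ly-HSCs on the x axis and My-HSCs on the y axis, with a dotted diagonal of equal effects and labels on genes called in either subset. Most points lie above 0 on both axes, 39 of 41 in Ly-HSCs and 38 of 41 in My-HSCs.

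The age effects of the subsets share no library. Called increases overlapped at 8 genes, Gda, Cd74, Eya4, Bmpr1a, Plscr2, Mab21l2, Rorb and the muscarinic receptor Chrm3, against 0.0713 expected for independent lists of 37 and 21 genes among 10900. The lists are not fully independent, since the numbers pair old libraries of the subsets. Both contrasts also use the same estimate of each gene's spread, from 1 fit, so the expected number may be too low. No gene was called down in both or in opposite directions. Across genes, which are not independent replicates, the fold changes correlated at a Pearson r of 0.276 and a Spearman rho of 0.229. The 37 genes higher in old Ly-HSCs had a median log2 fold change of 2.88 there and 1.54 in My-HSCs, with 32 higher. All 21 genes higher in old My-HSCs were also higher in Ly-HSCs, with medians of 2.82 in My-HSCs and 1.152 in Ly-HSCs. Without young Ly-HSC library 1 or 2 the overlap was 12 and 13, and without old Ly-HSC library 1, 2 or 3 it was 4, 3 and 3. Without young My-HSC library 1, 2 or 3 it was 2, 3 and 5, and without old My-HSC library 1, 2 or 3 it was 1, 0 and 0. The test of the difference itself, the interaction, called 0 genes by limma, with 616 at an unadjusted p under 0.05 and a smallest adjusted p of 0.656. The 10 genes with the smallest p did not pass, and 9 of them had an adjusted p of 0.682. They were Zfp456 (interaction -3.66 ± 0.63 on the log2 scale), Cept1 (-3.26 ± 0.66), Slfn9 (-1.97 ± 0.41), the proteasome subunit Psma5 (1.99 ± 0.42) and the collagen hydroxylase P3h2 (-3.15 ± 0.67), followed by Gadd45b (-3.19 ± 0.71), Zfp92 (-2.85 ± 0.64), Fam214b (-3.15 ± 0.71), the condensin subunit Ncaph (-3.29 ± 0.75) and the tight junction claudin Cldn5 (3.36 ± 0.78). In lists, the interaction called 4, of which cell cycle genes had the smallest p, with 7 of 47 positive and a median of -1.03 (camera adjusted p = 1.33e-06, and adjusted p = 0.621 with an estimated correlation).

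Over both subsets together, age raised Eya4 by 4.20 ± 0.33 on the log2 scale (adjusted p = 7.33e-05), Plscr2 by 3.71 ± 0.38 and Aldh1a1 by 2.73 ± 0.29 (both adjusted p = 5.19e-04). It raised Selp by 3.26 ± 0.43 (adjusted p = 0.00313) and Gda by 1.82 ± 0.21 (adjusted p = 0.00102). In the antigen presentation list Cd74 rose by 1.95 ± 0.17 (adjusted p = 9.29e-05). H2-Aa, a class II alpha chain, rose by 2.94 ± 0.53 (adjusted p = 0.0179). It stood at 5.74, 2.97 and 13.3 FPKM in young Ly-HSCs, 0, 7.53 and 7.79 in young My-HSCs, against 70.0, 72.0 and 32.3 in old Ly-HSCs and 27.9, 47.5 and 22.8 in old My-HSCs. The immunoproteasome subunit Psmb8 rose by 0.84 ± 0.15 (adjusted p = 0.0179) and H2-Q7 by 0.62 ± 0.11 (adjusted p = 0.0159). In the megakaryocyte list Selp, Clu (1.84 ± 0.32, adjusted p = 0.0170), the platelet integrin Itgb3 (1.67 ± 0.34, adjusted p = 0.0384), Plek (1.16 ± 0.20, adjusted p = 0.0150) and the multimerin Mmrn1 (0.65 ± 0.12, adjusted p = 0.0236) rose. Nes fell by 1.83 ± 0.29 (adjusted p = 0.00985) and Dtnbp1 by 0.80 ± 0.12 (adjusted p = 0.00657). Chosen after their values were seen, the sulfate transporter Slc26a11 fell by 1.80 ± 0.32 (adjusted p = 0.0179) and the insulin-degrading enzyme Ide by 0.97 ± 0.19 (adjusted p = 0.0274).

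Of the lists, HSC ageing genes rose over both subsets with 39 of 41 higher and a median of 1.58 (camera adjusted p = 9.71e-26, and adjusted p = 0.00120 with an estimated correlation). 18 members were called up, and with p adjusted over the list alone 28 rose and 1 fell. Antigen presentation genes rose with 17 of 18 higher and a median of 0.46 (camera adjusted p = 2.46e-06, and adjusted p = 0.0252 with an estimated correlation). Its called members, 5, all rose, as did 8 with p adjusted over the list alone. Camera called 10 further lists, each of which lost the call with an estimated correlation. Lists higher than other genes, each with its adjusted p and then its adjusted p with an estimated correlation, were myeloid priming (0.0158, 0.552), megakaryocyte and platelet (0.0304, 0.393), NF-kB (0.0304, 0.457), immediate early (0.0304, 0.508), heat shock (0.0304, 0.457), nuclear oxidative phosphorylation (0.0178, 0.289), granulocytes (0.0304, 0.457) and cell cycle (0.0178, 0.540). Lists lower were chromatin regulators (0.0178, 0.289) and HSC identity (0.0312, 0.457). Without the 4 libraries numbered 1, 7 of these were not called, among them myeloid priming (adjusted p = 0.916), NF-kB (adjusted p = 0.520), cell cycle (adjusted p = 0.991) and granulocytes (adjusted p = 0.242). All 10 lost the call without old Ly-HSC library 1 (adjusted p from 0.0601 to 0.108), 8 without young Ly-HSC library 2 (0.0514 to 0.134), and 6 each without young Ly-HSC library 1 (0.0786 to 0.2196), young My-HSC library 1 (0.0660 to 0.129) or old My-HSC library 1 (0.0645 to 0.137). Without young My-HSC library 2, 3 lost it (0.0549 to 0.0876), and without old My-HSC library 2 megakaryocyte (0.0534) and heat shock genes (0.0675). The megakaryocyte call also ended without old Ly-HSC library 2 (0.0816) or young Ly-HSC library 3 (0.0937), and the HSC identity call without young My-HSC library 3 (0.0676). The NF-kB member Ptgs2, the inducible cyclooxygenase, rose by 3.47 ± 0.66 (adjusted p = 0.0274) and Socs3, a feedback inhibitor of cytokine signalling, by 2.53 ± 0.49 (adjusted p = 0.0276). Ptgs2 stood at 39.7, 1.12 and 7.43 FPKM in old Ly-HSC libraries 1, 2 and 3 and at 51.8, 5.29 and 20.8 FPKM in the old My-HSC libraries, against at most 0.801 FPKM in a young one. Socs3 stood at 22.5, 5.90 and 11.4 and at 73.0, 19.0 and 32.5 FPKM. The libraries numbered 1, where both were highest, were also those highest in Itgam, at 159.98 FPKM in old Ly-HSCs and 124.5 FPKM in old My-HSCs against at most 33.0 FPKM elsewhere.

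In all, 92 genes were called over both subsets, 82 higher and 10 lower, with 1597 at an unadjusted p under 0.05. The split was 75 and 11 with median-of-ratios scaling, 66 and 11 as TPM and 62 and 22 with quantile normalization, which moved the median log2 fold change of all genes from 0.13 to -0.018. The count was 197 without young Ly-HSC library 2, 51 and 50 without old Ly-HSC library 2 or 3, 59 without young My-HSC library 1, and 58, 42 and 45 without old My-HSC library 1, 2 or 3. Without the 4 libraries numbered 1 it was 39. The fit treats all 12 libraries as independent, while the numbers pair old libraries of the subsets. The spread may therefore be understated for this mean over both subsets.

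The comparison of My-HSCs with Ly-HSCs in young mice gives the difference between the fractions before ageing. P3h2 was 13.96-fold higher in My-HSCs, at 17.2 ± 6.56 against 0.243 ± 0.159 FPKM (log2 fold change 3.80 ± 0.48, adjusted p = 0.0221). Vwf, which encodes von Willebrand factor of platelets and megakaryocytes, was 10.6-fold higher, at 29.6 ± 6.26 against 2.63 ± 2.83 FPKM (adjusted p = 0.0311). Sdpr was 8.44-fold higher at 37.4 ± 6.87 against 4.64 ± 3.597 FPKM (adjusted p = 0.0311). The focal adhesion protein Tns2 was 5.08-fold higher at 56.4 ± 15.7 against 11.9 ± 8.25 FPKM (adjusted p = 0.0484), and Gda 3.36-fold at 32.5 ± 1.51 against 9.75 ± 4.54 FPKM (adjusted p = 0.0484). On GRCm38, P3h2 lies on chromosome 16 from 25959288 to 26105784 and Vwf on chromosome 6 from 125546774 to 125686679.

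The activin subunit Inhba was listed at 0.081, 0 and 0 FPKM in Ly-HSCs and at 11.6, 14.1 and 14.1 FPKM in My-HSCs (adjusted p = 0.0236). Chil5 was listed at 0 in all 3 Ly-HSC libraries and at 20.8, 7.92 and 7.28 FPKM in My-HSCs (adjusted p = 0.0393). Gadd45b stood at 0, 1.84 and 0 against 13.1, 17.1 and 16.6 FPKM (adjusted p = 0.0236). Zfp456 stood at 0, 0.712 and 0.068 against 10.1, 14.2 and 10.9 FPKM (adjusted p = 0.0221) and Cept1 at 0, 1.65 and 0.107 against 13.6, 8.64 and 9.73 FPKM (adjusted p = 0.0311). The vesicular glutamate transporter Slc17a8 stood at 0, 0.017 and 0 against 9.83, 6.73 and 5.15 FPKM (adjusted p = 0.0260). Slamf1, which encodes the CD150 of the gate, was higher in My-HSCs without passing, at 23.3 ± 9.71 against 2.66 ± 1.93 FPKM (log2 fold change 2.78 ± 0.52, adjusted p = 0.0580). Flt3 stood at -2.35 ± 0.72 (adjusted p = 0.190), Cd48 at -0.81 ± 0.82 (adjusted p = 0.700) and Ly6a at 1.79 ± 0.55 (adjusted p = 0.188).

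The HSC ageing and lymphoid priming lists were called in young mice. The first includes Slamf1 of the CD150 gate. HSC ageing genes were higher in My-HSCs at 36 of 41 genes, with a median of 0.96 (camera adjusted p = 7.03e-08, and adjusted p = 0.0627 with an estimated correlation). Its called members Sdpr, Vwf and Gda were higher, and 12 were with p adjusted over the list alone. Lymphoid priming genes were lower in My-HSCs, with 5 of 15 higher and a median of -0.34 (camera adjusted p = 0.00644, and adjusted p = 0.545 with an estimated correlation). No member was called and 3 were lower with p adjusted over the list alone: the transcription factor Sox4 stood at 101.2 ± 10.5 in My-HSCs against 220.3 ± 57.8 FPKM in Ly-HSCs (adjusted p = 0.0902). The lymphoid call ended without young Ly-HSC library 3 (adjusted p = 0.333) and with only the genes above 0 in all 12 libraries (adjusted p = 0.0853). The other lists had adjusted p from 0.0993, for megakaryocyte and platelet genes, to 0.980. Among them HSC identity genes (adjusted p = 0.312) included Hoxb5, listed at 0, 0.356 and 0 against 9.76, 4.64 and 10.7 FPKM (adjusted p = 0.0775). The antigen presentation list (adjusted p = 0.328) included the peptide loading factor H2-DMa at -1.69 ± 0.32 (adjusted p = 0.0585).

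In all, 13 genes were called, each of them higher in young My-HSCs, with 1504 at an unadjusted p under 0.05. The median log2 fold change of all genes was 0.14, and 0.009 with quantile normalization and 0.21 as TPM. With relative depth as a covariate 1 gene was called, which is not among the 13, and 0 of the 11 named called genes passed (limma, 1097 at p under 0.05). Libraries did not overlap at 13.4% of genes, against 10% by chance. On simulated data 24.3% of the genes called in this contrast were false, and with 1 weight per group limma called 0 genes (724 at p under 0.05). With the replicate block within age 0 genes were called (1574 at p under 0.05). Leaving out young Ly-HSC library 1, 2 or 3 gave 55, 299 and 75 called genes, with all 11 named called genes passing each time. The count was 4 and 0 without old Ly-HSC library 2 or 3, 0, 0 and 1 without young My-HSC library 1, 2 or 3, and 3, 0 and 0 without old My-HSC library 1, 2 or 3. For these counts of 0, in the order given, 1324, 1212, 1330, 1292 and 1284 genes had an unadjusted p under 0.05.

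The comparison of My-HSCs with Ly-HSCs in old mice gives the difference between the fractions at 18 months. Clu was 16.2-fold higher in My-HSCs, at 30.4 ± 9.98 against 0.888 ± 0.369 FPKM (log2 fold change 4.02 ± 0.45, adjusted p = 0.00724). Fgd5, a Cdc42 exchange factor used as an HSC marker, was 2.39-fold higher, at 60.4 ± 0.604 against 24.8 ± 0.965 FPKM (adjusted p = 0.0233). Runx3, a Runt-domain transcription factor of lymphoid development, was lower in My-HSCs by -2.02 ± 0.30 on the log2 scale, at 8.03 ± 1.14 against 35.8 ± 5.26 FPKM (adjusted p = 0.0429). On GRCm38, Clu lies on chromosome 14 from 65968483 to 65981547, Fgd5 on chromosome 6 from 91978878 to 92076004 and Runx3 on chromosome 4 from 135120652 to 135177990.

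The 10 genes next by p did not pass. Cldn5 was listed at 0 in all 3 old Ly-HSC libraries and at 12.6, 14.9 and 4.94 FPKM in old My-HSCs. Cldn5, Rbpjl at 2.42 ± 0.40 and Osmr at 2.10 ± 0.35 had an adjusted p of 0.0777. The other 7 had an adjusted p of 0.103. The sialomucin Cd34 stood at 8.46 ± 3.65 in My-HSCs against 37.0 ± 4.88 FPKM in Ly-HSCs, the transcription factor Mllt3 at 46.4 ± 3.37 against 22.4 ± 1.34 FPKM. The others were Matn4 (2.74 ± 0.49), Gpr183 (2.96 ± 0.54), Tc2n (2.40 ± 0.44), Hoxb8 (3.00 ± 0.55) and the potassium channel Kcnb2 (1.95 ± 0.36). Slamf1 stood at 30.9 ± 4.46 against 5.53 ± 3.38 FPKM (2.45 ± 0.52, adjusted p = 0.202), Flt3 at -2.16 ± 0.72 (adjusted p = 0.790), Cd48 at -1.06 ± 0.82 and Ly6a at 0.28 ± 0.55 (adjusted p = 1 for both).

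HSC ageing genes were higher in old My-HSCs at 40 of 41 genes, with a median of 1.32 (camera adjusted p = 2.45e-38, and adjusted p = 2.73e-04 with an estimated correlation). Clu was the 1 called member, and 21 were higher with p adjusted over the list alone. The list includes Slamf1 of the CD150 gate. The 9 other called lists lost the call with an estimated correlation. HSC identity genes were higher in My-HSCs at 23 of 24, with a median of 0.36 (camera adjusted p = 1.40e-09, and adjusted p = 0.0595 with an estimated correlation). Fgd5 was called, and 5 were higher with p adjusted over the list alone. Cell cycle genes were lower in My-HSCs, with 3 of 47 higher and a median of -0.50 (camera adjusted p = 7.97e-09, and adjusted p = 0.207 with an estimated correlation). None was called: the replication helicase subunits Mcm7 and Mcm5 stood at -0.85 ± 0.25 (adjusted p = 0.570) and -0.96 ± 0.32 (adjusted p = 0.793). Megakaryocyte and platelet genes were higher at 15 of 24, with a median of 0.29 (camera adjusted p = 0.00601, and adjusted p = 0.207 with an estimated correlation). This list shares 5 genes with the HSC ageing list, Clu was its 1 called member, and 6 were higher and 2 lower with p adjusted over the list alone. Immediate early genes were higher at 11 of 15, with a median of 0.47 (camera adjusted p = 0.00449, and adjusted p = 0.477 with an estimated correlation), with Cyr61 at 2.43 ± 0.49 (adjusted p = 0.146). Their call ended with only the genes above 0 in all 12 libraries (adjusted p = 0.0989).

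Lymphoid priming genes were lower in old My-HSCs, with 5 of 15 higher and a median of -0.21 (camera adjusted p = 0.00449, and adjusted p = 0.207 with an estimated correlation). Sox4 stood at 72.5 ± 23.3 against 173.3 ± 23.9 FPKM (adjusted p = 0.120) and was the 1 member lower with p adjusted over the list alone. The call ended without old My-HSC library 3 (adjusted p = 0.0737). Antigen presentation genes were lower, with 2 of 18 higher and a median of -0.18 (camera adjusted p = 0.00449, and adjusted p = 0.177 with an estimated correlation). Tap2, a peptide transporter subunit, stood at -0.65 ± 0.17 (adjusted p = 0.385). The call ended with quantile normalization (adjusted p = 0.0675) and without old Ly-HSC library 2 (adjusted p = 0.0551) or old My-HSC library 3 (adjusted p = 0.0638). DNA repair genes were lower, with 8 of 39 higher and a median of -0.21 (camera adjusted p = 0.00601, and adjusted p = 0.477 with an estimated correlation). That call ended without old Ly-HSC library 2 (adjusted p = 0.169) or old My-HSC library 3 (adjusted p = 0.0570). Chromatin regulators were lower, with 11 of 40 higher (camera adjusted p = 0.0436, and adjusted p = 0.276 with an estimated correlation). Their call ended with the replicate block within age (adjusted p = 0.0545) and without old Ly-HSC library 2 (adjusted p = 0.154) or 3 (adjusted p = 0.162) or old My-HSC library 2 (adjusted p = 0.116) or 3 (adjusted p = 0.0827). Erythroid genes were lower, with 3 of 12 higher (camera adjusted p = 0.0436, and adjusted p = 0.554 with an estimated correlation). The erythroid transcription factor Klf1 was listed at 21.6, 7.21 and 0.421 FPKM in old Ly-HSC libraries 1, 2 and 3 and at 2.59, 0.187 and 0 FPKM in old My-HSCs, and Hemgn stood at -0.72 ± 0.40 (adjusted p = 1 for both). The list turned to the other direction without old Ly-HSC library 1 (adjusted p = 0.864). Their call also ended without old My-HSC library 2 (adjusted p = 0.445) or 3 (adjusted p = 0.349), and without young Ly-HSC library 1 (adjusted p = 0.0710) or 3 (adjusted p = 0.0666) or young My-HSC library 1 (adjusted p = 0.0625). It ended as well with the replicate block (adjusted p = 0.0565), with genes above 0 in all 12 libraries (adjusted p = 0.504) and without the 4 libraries numbered 1 (adjusted p = 0.0813). The 19 uncalled lists ran from an adjusted p of 0.0910 to 0.982.

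In all, 3 genes were called in old mice, 2 higher and 1 lower in My-HSCs, with 439 at an unadjusted p under 0.05, and libraries did not overlap at 16.7% of genes, against 10% by chance. Quantile normalization called 7 higher and 1 lower. With the replicate block within age (numbers that pair old libraries by the data, not by a label), limma called 0 genes (462 at p under 0.05). With 1 weight per group, 69 genes were called, 49 higher and 20 lower, with the 3 among them, and on simulated data 0.6% of the genes called with equal weights were false. The count was 5, 5 and 6 without young Ly-HSC library 1, 2 or 3, and 0 without old Ly-HSC library 1, 2 or 3 (312, 426 and 386 genes at p under 0.05). It was 1 without young My-HSC library 2 or old My-HSC library 1, and 0 without old My-HSC library 2 or 3 (318 and 301 genes at p under 0.05). Without the 4 libraries numbered 1 it was also 0 (541 genes at p under 0.05).

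**Figure D3:**
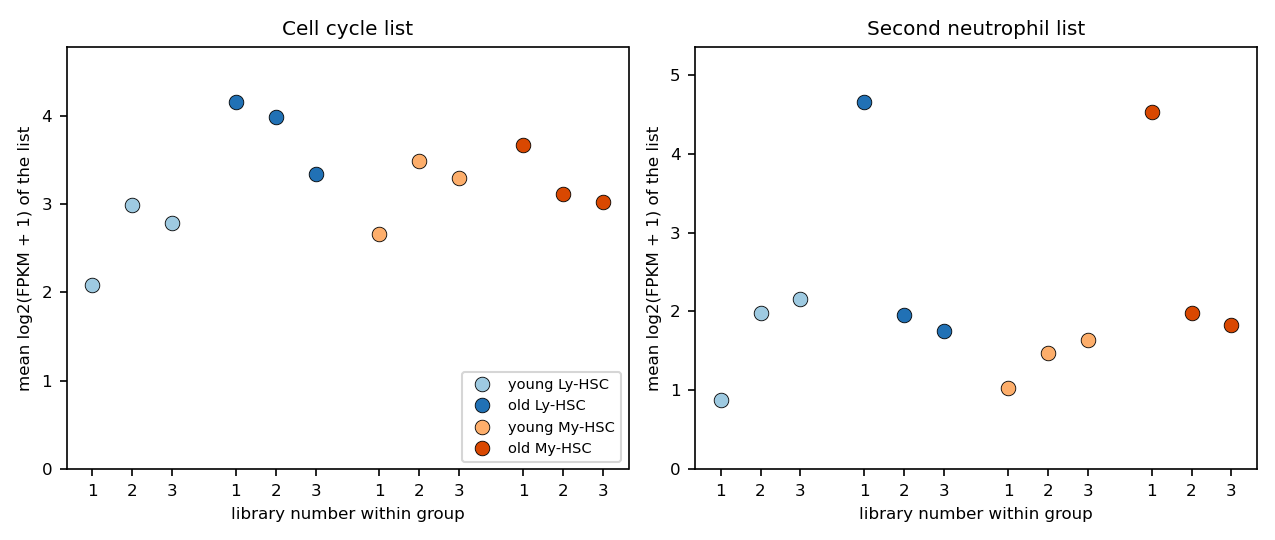
Mean log2(FPKM + 1) over the genes of the cell cycle list and of a neutrophil marker list, with 1 point per library and the 4 groups along the x axis. The cell cycle mean is 4.16, 3.98 and 3.34 in old Ly-HSC libraries 1, 2 and 3 and at most 3.67 elsewhere, and the neutrophil mean is 4.66 and 4.53 in the old libraries numbered 1 and at most 2.15 elsewhere.

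The subset effects at the 2 ages share no library, but they use the same estimate of each gene's spread. No gene was called alike in both, against 0.00239 expected for lists of 13 and 2 genes, and the fold changes correlated across genes at a Pearson r of 0.188 and a Spearman rho of 0.165. Without young Ly-HSC library 1, 2 or 3, however, 2, 3 and 2 genes were called alike. Of the 13 genes higher in young My-HSCs, 11 were also higher in old My-HSCs, with a median log2 fold change of 1.17 there. Over both ages together, My-HSCs held more Vwf (3.12 ± 0.38, adjusted p = 0.00476), Clu (3.05 ± 0.32, adjusted p = 0.00329), Slamf1, which encodes the CD150 of the gate (2.62 ± 0.37, adjusted p = 0.00810), and Sdpr (2.40 ± 0.34, adjusted p = 0.00810). They also held more Gda (1.64 ± 0.21, adjusted p = 0.00493), Fgd5 (0.97 ± 0.12, adjusted p = 0.00476), Mmrn1 (0.81 ± 0.12, adjusted p = 0.0120) and the homeobox gene Hoxb5 (2.40 ± 0.46, adjusted p = 0.0437). They held less Sox4, which stood at -1.19 ± 0.18 (adjusted p = 0.0120). Chosen after their values were seen, Runx3 stood at -1.71 ± 0.21 (adjusted p = 0.00476), Cd34 at -1.87 ± 0.26 (adjusted p = 0.00810), each lower in My-HSCs. So were the costimulatory receptor Cd27 at -1.12 ± 0.17 (adjusted p = 0.0140) and the tetraspanin Cd37 at -1.50 ± 0.26 (adjusted p = 0.0267).

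Over both ages, HSC ageing genes were higher in My-HSCs at 38 of 41, with a median of 1.08 and 10 members called (camera adjusted p = 1.06e-24, and adjusted p = 0.00140 with an estimated correlation). Slamf1, 1 of the 10, encodes the CD150 by which the subsets were sorted, so its difference follows from the sort. HSC identity genes were higher at 21 of 24, with a median of 0.30 and 3 called (camera adjusted p = 7.21e-05, and adjusted p = 0.180 with an estimated correlation). With p adjusted over the list alone 10 were higher and 1 lower. Lymphoid priming genes were lower, with 2 of 15 higher, a median of -0.33 and Sox4 called (camera adjusted p = 2.04e-04, and adjusted p = 0.180 with an estimated correlation). Megakaryocyte genes were higher with 3 called (camera adjusted p = 0.0101, and adjusted p = 0.232 with an estimated correlation) and antigen presentation genes lower (camera adjusted p = 0.0101, and adjusted p = 0.180 with an estimated correlation). These last calls ended without young Ly-HSC library 2 (megakaryocyte, adjusted p = 0.0729) and without young Ly-HSC library 3 (antigen presentation, adjusted p = 0.194), and the latter also with quantile normalization (adjusted p = 0.226). In all, 45 genes were called, 35 higher and 10 lower in My-HSCs, with 1217 at an unadjusted p under 0.05, and 17 with the replicate block within age. Of the genes named above, Vwf, Clu, Slamf1, Sdpr, Gda, Fgd5, Runx3, Cd34 and Cd27 passed with that block, and Mmrn1, Sox4 and Cd37 (adjusted p = 0.0687 each) and Hoxb5 (adjusted p = 0.0895) did not. The count was 88 and 111 without young Ly-HSC library 1 or 2, 17, 17 and 18 without old Ly-HSC library 1, 2 or 3, and 15 and 14 without old My-HSC library 2 or 3.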

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

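In this part the comparisons with random gene lists were chosen after the result was seen. Camera, applied to the test of whether the age effect differs between the subsets, called 4 of 29 lists, although limma called 0 single genes there (616 at an unadjusted p under 0.05). HSC identity genes lay higher in the interaction than the other genes, with 16 of 24 positive and a median of 0.11, from median age effects of -0.14 in Ly-HSCs and -0.032 in My-HSCs (adjusted p = 0.0473, and adjusted p = 0.812 with an estimated correlation). That call ended without young Ly-HSC library 1 (adjusted p = 0.181) or 2 (adjusted p = 0.388), old Ly-HSC library 1 (adjusted p = 0.0929), young My-HSC library 2 (adjusted p = 0.229) or old My-HSC library 2 (adjusted p = 0.0869) or 3 (adjusted p = 0.0988). It also ended with the replicate block (adjusted p = 0.0536), with quantile normalization (adjusted p = 0.286), with a pseudocount of 0.1 (adjusted p = 0.0560) and without the 4 libraries numbered 1 (adjusted p = 0.0544). HSC ageing genes lay higher in the interaction too, with 25 of 41 positive and a median of 0.28 (adjusted p = 0.0133, and adjusted p = 0.621 with an estimated correlation). Their call ended without young Ly-HSC library 1 (adjusted p = 0.0611), without the 4 libraries numbered 1 (adjusted p = 0.0544), with genes above 0 in all 12 libraries (adjusted p = 0.435) and with a pseudocount of 0.1 (adjusted p = 0.646). DNA repair genes lay lower in the interaction, with 11 of 39 positive and a median of -0.38, from median age effects of 0.26 in Ly-HSCs and -0.18 in My-HSCs (adjusted p = 0.0220, and adjusted p = 0.812 with an estimated correlation). The DNA repair call ended with a pseudocount of 0.1 (adjusted p = 0.0560) and without young Ly-HSC library 1 (adjusted p = 0.0611), old Ly-HSC library 2 (adjusted p = 0.166), young My-HSC library 2 (adjusted p = 0.189) or old My-HSC library 3 (adjusted p = 0.0547). All 100 drawn splits of the libraries gave at least the 0 called genes of the interaction, as any split must, so they say nothing about chance there. The highest other split, which exchanged the age labels in 1 subset and so tests age over both subsets, gave 92 and points to the age structure of the libraries.

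The fourth list, cell cycle genes, rose more with age in Ly-HSCs, with 7 of 47 positive and a median interaction of -1.03 (adjusted p = 1.33e-06, and 0.621 with an estimated correlation, the 1 alternative that ended the call). A candidate explanation is that young Ly-HSC libraries are poor in low-level transcripts, but the list's median change with age in Ly-HSCs, 1.145, lay outside the middle 95% of 10000 random lists matched on level, 0.016 to 0.524. The difference between old My-HSCs and old Ly-HSCs, which uses no young library, was -0.502, also outside that range for random lists, -0.109 to 0.18. The list thus moved further than unrelated genes of its level. Random lists hold genes that need not vary together, so their range is too narrow for a list that does. The comparison therefore does not decide whether poor young libraries moved the list as a block. Variation of the whole list from library to library stays open, since the lowest old Ly-HSC library had a list mean of 3.341 and old My-HSC library 1 a higher one of 3.672, and old Ly-HSC library 1, which also holds mature-cell transcripts, had the highest, 4.155, although the interaction call did not end without it. A change in the cycling of Ly-HSCs with age, which the design would allow, was not tested and stays open as well.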

How the results depend on the processing

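Chosen after seeing the data were the fits without the 4 libraries numbered 1, without the 4 lowest-weight libraries, with genes above 0 in all 12 libraries, with depth as a covariate, with a pseudocount of 5 and with 1 weight per group. Over 35 alternatives, 12 of them leaving out 1 library, the 18 counts, overlaps and correlations kept their value within 1.5 times or within the spread in 254 of 441 cases, fell below in 113, rose above in 58 and moved in 16, and 0 turned direction. Only the correlations among them could turn, since a count has no direction. Of 855 list tests 692 kept their call and direction, 162 lost the call and 1 turned direction, and of 1516 folds of named called genes 933 kept the call, 583 lost it and 0 turned direction. The libraries of these genes did not overlap between the groups compared. Leaving out a library, weights, blocks or another variance model could therefore not turn a fold, and that 0 adds no support. Where fewer libraries or genes were used, that is what changed. TPM acted much as a smaller pseudocount, and for the others the cause was not tested. Leaving out 1 library leaves 2 in a group, with the spread pooled over groups. Of 167 named genes 71 were listed at 0 in at least 1 library, and how much of this comes from depth was not settled.

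The count of called genes for age in Ly-HSCs was 38, and 20 with a pseudocount of 5, 17 with a mean FPKM of at least 5, 10 with genes above 0 in all 12 libraries, 24 with median-of-ratios scaling, 14 with quantile normalization, 60 with no trend, 22 with array weights and 9 with group weights. It was 0 with only the groups compared (limma, 950 at p under 0.05), 15 with the replicate block, 11 without the 4 libraries numbered 1, 251 without the 4 lowest-weight libraries and 3 with depth as a covariate. Leaving out 1 library gave 7 (old Ly-HSC library 2) to 223 (young Ly-HSC library 2). For age in My-HSCs the count was 23, and 1 with a pseudocount of 0.1, 45 with a pseudocount of 5, 56 with no filter, 7 with a mean FPKM of at least 5, 7 with genes above 0 in all 12 libraries, 1 as TPM, 227 with array weights and 71 with group weights. It was 36 with only the groups compared, 9 with the replicate block, 4 without the 4 libraries numbered 1 and 75 without the 4 lowest-weight libraries, and 0 (old My-HSC library 2, limma, 576 at p under 0.05) to 36 (young Ly-HSC library 1) leaving out 1 library.

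For subset in young mice the count was 13, and 22, 7 and 20 with pseudocounts of 0.1, 0.5 and 5, 2 with no filter, 1 with genes above 0 in all 12 libraries, 56 with no trend, 0 with group weights (limma, 724 at p under 0.05) and 0 with only the groups compared (780). It was 4 with the replicate block, 0 with the replicate block within age (1574), 57 with a random replicate block, 32 without the 4 libraries numbered 1, 284 without the 4 lowest-weight libraries and 1 with depth as a covariate. Leaving out 1 library gave 0 (old Ly-HSC library 3, 1324 at p under 0.05) to 299 (young Ly-HSC library 2). For subset in old mice the count was 3, and 1 and 13 with pseudocounts of 0.1 and 5, 29 with no filter, 1 with genes above 0 in all 12 libraries, 8 with quantile normalization, 15 with no trend, 454 with array weights, 69 with group weights and 12 with only the groups compared. It was 1 with the replicate block, 0 with the replicate block within age (limma, 462 at p under 0.05), 0 without the 4 libraries numbered 1 (541) and 12 without the 4 lowest-weight libraries, and 0 (old Ly-HSC library 1, 312 at p under 0.05) to 6 (young Ly-HSC library 3) leaving out 1 library.

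The interaction count was 0, with 6 for no filter and 1 without the 4 lowest-weight libraries. For age over both subsets the count was 92, and 60 with a mean FPKM of at least 5, 46 with genes above 0 in all 12 libraries, 154 with array weights, 39 without the 4 libraries numbered 1, 374 without the 4 lowest-weight libraries and 37 with depth as a covariate. Leaving out 1 library gave 42 (old My-HSC library 2) to 197 (young Ly-HSC library 2). For subset over both ages the count was 45, and 69 with no filter, 27 with genes above 0 in all 12 libraries, 112 with array weights, 17 with the replicate block within age, 79 with a random replicate block, 207 without the 4 lowest-weight libraries and 26 with depth as a covariate. Leaving out 1 library gave 14 (old My-HSC library 3) to 111 (young Ly-HSC library 2). On simulated data the share of false calls with array weights was 6.2%, 3.4%, 4.1% and 4.6% for age in Ly-HSCs, age in My-HSCs, subset in young and subset in old mice.

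The count of called lists was 4 for age in Ly-HSCs, 7 for age in My-HSCs, 2 and 10 for subset in young and old mice, 4 for the interaction, 12 for age over both subsets and 5 for subset over both ages. With an inter-gene correlation estimated it was 1, 2, 0, 1, 0, 2 and 1 in that order. With genes above 0 in all 12 libraries it was 7 for age in Ly-HSCs, 1 for subset in young mice and 5 for age over both subsets, and without the 4 libraries numbered 1 it was 4 for subset in young mice and 5 for age over both subsets. With quantile normalization it was 11 for age in My-HSCs and 5 for subset in young mice, and with a pseudocount of 0.1 it was 1 for the interaction. Leaving out 1 library gave 3 to 10 for age in Ly-HSCs, 4 to 9 for age in My-HSCs, 1 to 4 for subset in young mice, 5 to 14 for subset in old mice, 2 to 7 for the interaction, 2 (old Ly-HSC library 1) to 14 for age over both subsets and 4 to 8 for subset over both ages. The erythroid list in old mice went from an adjusted p of 0.0436 to 3.21e-06 without old My-HSC library 1, and turned to the other direction without old Ly-HSC library 1 (adjusted p = 0.864). The replicate block within age ended the chromatin call in old mice (adjusted p = 0.0545) and no other list call of the subset contrasts within an age.

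The correlation of the age effects was 0.276, and 0.315 with a pseudocount of 0.1, 0.225 without the 4 libraries numbered 1, 0.243 with genes above 0 in all 12 libraries and 0.2255 to 0.282 leaving out 1 library. The overlap of age calls was 8, and 1 with a pseudocount of 0.1, 5 with the replicate block, 2 without the 4 libraries numbered 1, 3 with genes above 0 in all 12 libraries and 0 (old My-HSC library 2) to 13 (young Ly-HSC library 2) leaving out 1 library. The correlation of the subset effects was 0.188, and 0.2099 without the 4 libraries numbered 1 and 0.148 to 0.212 leaving out 1 library, and the overlap of subset calls was 0, and 0 to 3 (young Ly-HSC library 2) leaving out 1 library. Of the 18 named called genes for age in Ly-HSCs, 10 passed with the replicate block and 6 without the 4 libraries numbered 1, and of the 16 for age in My-HSCs 8 and 3.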

Other observations

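In this part the genes of this paragraph, the comparisons with random gene lists, the splits that follow the library numbers and the tests and rules named below as later ones were chosen after the values or the result were seen. Over both ages, with the replicate block within age, Cd27 and Cd34 below still differed between My-HSCs and Ly-HSCs (adjusted p = 0.0384 and 0.0424), while Cd37 (0.0687), Neo1 (0.0771), Cd38 (0.0698), Hoxb8 (0.0543) and Mllt3 (0.121) did not pass. Without that block, the costimulatory receptor Cd27 stood at 164.3 ± 27.6 and 128.8 ± 19.3 FPKM in young and old Ly-HSCs against 71.0 ± 23.8 and 64.5 ± 13.6 FPKM in young and old My-HSCs (n = 3 each, adjusted p = 0.0140). The tetraspanin Cd37 stood at 40.2 ± 5.85 and 38.3 ± 5.46 against 14.6 ± 6.10 and 13.9 ± 8.497 FPKM (adjusted p = 0.0267), and Cd34 at 52.0 ± 10.7 and 37.0 ± 4.88 against 16.6 ± 6.26 and 8.46 ± 3.65 FPKM (adjusted p = 0.00810). The netrin receptor Neo1 was higher in My-HSCs by 1.98 ± 0.33 on the log2 scale (adjusted p = 0.0210), the ectoenzyme Cd38 by 2.41 ± 0.44 (adjusted p = 0.0316), the homeobox gene Hoxb8 by 2.47 ± 0.39 (adjusted p = 0.0167), each of them listed at 0 in at least 1 young Ly-HSC library. Mllt3 was higher by 0.78 ± 0.14 (adjusted p = 0.0267). With age over both subsets, the metallothionein Mt1 rose by 2.97 ± 0.60 (adjusted p = 0.0346), the stress-responsive kinase Plk2 by 1.86 ± 0.33 (adjusted p = 0.0179), the transglutaminase subunit F13a1 by 2.21 ± 0.44 (adjusted p = 0.0317) and the glycolytic enzyme Ldha by 0.74 ± 0.13 (adjusted p = 0.0184). F13a1 also belongs to the fixed list of monocyte and macrophage markers, which were higher in both old libraries numbered 1, as described below.

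More genes were higher than lower with age in Ly-HSCs, 37 against 1 among called genes, and a candidate explanation is loss of transcripts at random in single young libraries. At 160 genes all 3 young Ly-HSC libraries were low, against 39.86 expected from each library's own rate, and this ratio of 4.014 would by the rule written in advance have left random loss sufficient (triples from 3 different groups had a median of 17.49 and a highest value of 280.7), but by a later rule the test decides nothing, since its ratio could not exceed 14.85. At 48 genes all 6 young libraries were low, against 0.0758 expected and at most 45 in 922 other sets of 6 libraries, and 32 of them were highest in the 2 old libraries numbered 1, whose mature-cell transcripts are described below. In a later test without the 4 libraries numbered 1, 27 genes were low in all 4 young libraries. The expected number was 0.435 and the highest of 68 other sets 11. By its rule this argues against loss at random in single libraries at these genes. However, the expected number treats libraries as independent, and the mixed triples above also exceeded such numbers. The other sets hold fewer young libraries, which had more genes at 0, so loss at random is not excluded. Of the 8 genes called in both subsets 6 were among the 27, which adds no support, since both choices use the same values. A loss shared by the young libraries is confounded with age and stays open. For the HSC ageing list, medians of 1.108 in Ly-HSCs and 1.822 in My-HSCs lay outside the middle 95% of random lists matched on level, -0.019 to 0.458 and -0.104 to 0.262. The list thus moved further than unrelated genes of its level. Random lists hold genes that need not vary together, so their range may be too narrow. Both list calls also stood in camera with an estimated correlation, but camera does not match genes on level. Whether poor young libraries moved the list is therefore not decided.

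Transcripts of mature blood cells were high in both old libraries numbered 1, where granulocyte markers exceeded the other old libraries by a median of 4.38 in Ly-HSCs and 3.84 in My-HSCs, B lineage markers by 2.21 and 2.13, erythroid genes by 2.00 and 1.53, mast cell and basophil markers by 1.53 and 2.26, monocyte and macrophage markers by 1.57 and 0.45 and T and NK markers by 0.30 and 1.31. A candidate source is RNA of neutrophil-lineage cells in the pool numbered 1, although the sort against Gr-1 would remove them, and a list of 21 tested neutrophil genes, from which a later rule left out genes of the fixed lists, exceeded the other libraries by 2.214 in Ly-HSCs, at 21 of 21 genes, and 2.686 in My-HSCs, at 20 of 21. Hp, Cd177 and Olfm4 stood at 132.56, 111.87 and 51 FPKM in old Ly-HSC library 1 and at 82.7, 72.91 and 27.54 FPKM in old My-HSC library 1, against at most 6.78, 2.58 and 1.43 FPKM in the other old libraries, while 9 of the 21 genes reached an FPKM of 1 in all 4 old libraries numbered 2 and 3, and 0 are in another list. The 42 genes of the fixed lists of other cells and of erythroid genes exceeded the other old libraries by 1.08 in My-HSCs and 1.55 in Ly-HSCs. The middle 95% of random lists reached 0.239 and 0.177 there. These lists also define the pattern, and 11 of the 42 genes reached an FPKM of 1 in all 4 old libraries numbered 2 and 3. Random lists hold genes that need not vary together. The comparison therefore does not decide whether greater spread of the libraries numbered 1 is the source. Which cells gave the B lineage and erythroid transcripts, and whether these mice differed in their blood, was not tested.

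Splits of the libraries were counted for each contrast. For the contrasts within a subset or an age, the 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 38 called genes for age in Ly-HSCs, 23 for age in My-HSCs, 13 for subset in young mice and 3 for subset in old mice, and the highest other split 0, 0, 1 and 0. Of 100 splits drawn within each subset, 1, the real one, gave as many as the 92 genes for age over both subsets (highest other 1). The numbers pair old libraries, however, and the splits that keep same-numbered libraries of an age together are 10, too few for a share under 0.05 (92 in the real split, highest other 0). Of 100 splits drawn within each age, 1, the real one, gave as many as the 45 genes for subset over both ages (highest other 0). Among the 32 splits that part every same-numbered pair, as the real one does, it was again 1 (highest other 0). Both shares are under 0.05, which argues against chance as the source of that count without excluding it.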
